A study of Mus musculus with 8 samples.

How the data were processed

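RNA was measured in 8 orthotopic tumours, 4 from vehicle-treated and 4 from CA-4948-treated mice, and each tumour was treated as a separate replicate because the study design gives 4 animals per condition. Per the labels' protocols, RNA was extracted with Trizol, mRNA was isolated with Dynal beads and libraries were made with a standard Illumina protocol. The submitters' processing notes name bcl2fastq, STAR 2.5.1a, Subread, featureCounts 1.4.6-p5 and edgeR, without roles, and the human build GRCh38. The deposited gene identifiers are mouse Ensembl identifiers. Of the identifiers found in the GENCODE M21 annotation of the mouse build GRCm38, 99.8% overlapped their gene there on the same chromosome, and 76.1% had the same start and end. Coordinates are therefore given as deposited, in GRCm38, 1-based. The counting settings for strand and for reads with several matches are not given in the sources used here, so values of near-identical or overlapping genes are uncertain.

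Each deposited file lists 41388 genes with a whole-number count, a CPM and an RPKM per gene, per the file headers. The deposited CPM equalled the count divided by the library's total, and the deposited RPKM equalled that CPM per kilobase of the deposited gene length, so only the counts were used for tests. Symbols came from the reference table for 40254 identifiers. Total counts ranged from 9878826 to 26672792 per library.

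Genes were kept by edgeR's filterByExpr, which left 30858. Scaling was by TMM on the counts of the kept genes, and CPM values in the text use the TMM-scaled library sizes. The arms were compared with edgeR 4.0.16 (glmQLFit with robust estimation, quasi-likelihood F test, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all kept genes and a threshold of 0.05. The 34 gene lists with at least 5 kept members, out of 35, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 34 lists. Of the 615 list symbols, 612 were matched. Tests, lists and the rule for named genes were fixed before the data were examined. The rule takes the 12 genes with the largest fold change per direction among genes past the threshold, with a mean of at least 1 CPM in an arm and no overlap between the arms. It leaves out predicted genes, pseudogenes and antigen receptor segments, and adds up to 4 members of each list by smallest p and 15 fixed genes of the pathway, the stroma, T cells and the tumour line. Of the list members so chosen, a part is given in the text.

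Relative levels were computed after the data had been examined. GC content was taken from the longest GENCODE M21 transcript of each gene and known for 98.4% of tested genes. Protein-coding genes were put into 20 bins of GC content, and each gene's count per kilobase was divided by its bin's median in the same library. The silent reference was 1378 olfactory, vomeronasal and taste receptor genes of at least 300 bases. The housekeeping index of a library is the geometric mean of the counts per kilobase of 10 housekeeping genes over the rate in those receptor genes. For the GC correction, each library's deviation from the gene mean log2 CPM was fitted by loess on GC content with a span of 0.3 and entered as an offset.

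Alternatives fixed beforehand were DESeq2 size factors, upper-quartile scaling and library size alone, the DESeq2 1.42.0 Wald test, limma voom, no filter or a filter of at least 1 CPM in 4 libraries, no robust estimation, the replicate number as a block, each library left out, an acinar marker covariate and removal of acinar, islet, erythroid and mitochondrial genes. For lists, an estimated correlation and fry were added, and for counts of genes a threshold of 0.1 and a minimum absolute log2 fold change of 1. After the data had been examined, the GC correction, a restriction to protein-coding genes at a relative level of at least 3, the housekeeping index as a covariate and omission of the libraries with the highest index in each arm were added. Under that restriction, library sizes, scaling and spread were estimated from the kept genes alone. To look for duplicated libraries, the counts of each pair of replicates of an arm were compared by chi-square, which takes every count as independent and covers counting error only. The statistic per degree of freedom was 3 to 13.9, and no pair was treated as duplicates.

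The method was tested on simulated counts for this comparison. Among 30132 genes with 50 changed at each size, 94% were recovered at a fold of 4, 56% at a fold of 2 and 10% at a fold of 1.5, and 10.6% of the genes called were unchanged. Depth also limits the values of single genes: the genes named from the lower calls had between 4 and 91 counts per library.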

Results

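RNA sequencing libraries were made from orthotopic pancreatic tumours of mice. KI cells, a pancreatic cancer line that the labels describe as from a KRAS/INK4A mouse, were injected at 100000 cells per animal into the pancreas of syngeneic mice. Once tumours could be felt, the animals received vehicle or CA-4948 for 14 days. CA-4948, also called emavusertib, inhibits IRAK4, the kinase that carries signals from Toll-like and interleukin-1 receptors through MyD88 to NF-kB. There were 4 tumours per arm, each a separate library. The comparison asks which transcripts of the tumour and of the tissue around it differ after IRAK4 inhibition.

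Total counts over the 41388 listed genes were 26672792, 20348590, 9878826 and 18387083 in vehicle replicates 1 to 4. They were 16552595, 22014109, 22018940 and 17786252 in CA-4948 replicates 1 to 4. Most of these counts lay in 9 unnamed loci, chosen because each held over 0.1% of the counts on average. The locus Gm10800 (ENSMUSG00000075014, chromosome 2, 98666547 to 98667301) alone held 51.2% to 61.9% of a library. Together the 9 loci held 77.3% ± 2.73 of the counts in vehicle and 82.4% ± 0.895 in CA-4948 tumours (SD, n = 4 each). No value of the vehicle arm reached the CA-4948 arm (two-sided exact permutation test, p = 0.0286, the smallest possible; adjusted p = 0.114 over 16 library measures). The 95% Wilson intervals of these shares were at most 0.062 percentage points wide and cover counting error only; whether the reads of a pair were counted separately is not given in the sources used here. Outside these loci and the mitochondrial genes, 2595393 to 5273851 counts per library remained.

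Single genes such as Actb and B2m were counted well above the level of silent genes, while most members of the gene lists were not. To describe this, each gene's counts per kilobase were divided by the median of protein-coding genes of like GC content in the same library, here called its relative level. Genes of smell and taste receptors, which a pancreatic tumour does not use, had a median relative level of 1.12 to 1.36 per library, and 97.0% to 98.0% of these 1378 genes had counts. Against that, Actb, the cytoskeletal actin, stood at 10.9 to 86.5 and Col1a1, a chain of fibrillar collagen, at 3.31 to 19.8. Krt18, a keratin of simple epithelium, stood at 2.69 to 13.5 and Vim, the mesenchymal filament protein, at 3.83 to 17.0. B2m, the light chain of class I antigen presentation, stood at 8.49 to 63.5. Of the antigen presentation genes 5 of 21 had a mean relative level of 3 or more, and of the collagen and matrix genes 4 of 26. The single genes named here apart from Col1a1 were picked after their values were seen. Averaged over the 8 libraries, 432 protein-coding genes reached a relative level of 3 or more, 85 of them receptor genes. The targets and effectors of the drug did not reach it: Irak4 lay at 0.944 to 1.44 per library and Il1b at 0.982 to 1.69. Among the genes of the housekeeping index, Ppia had a mean relative level of 0.917 and Tuba1b one of 2.39. The others of that index lay between 3.88 (Rplp0) and 30.4 (Actb). A relative level as low as that of the receptor genes therefore does not by itself show that a gene is not expressed. This reading rests on Ppia alone.

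**Figure D1:**
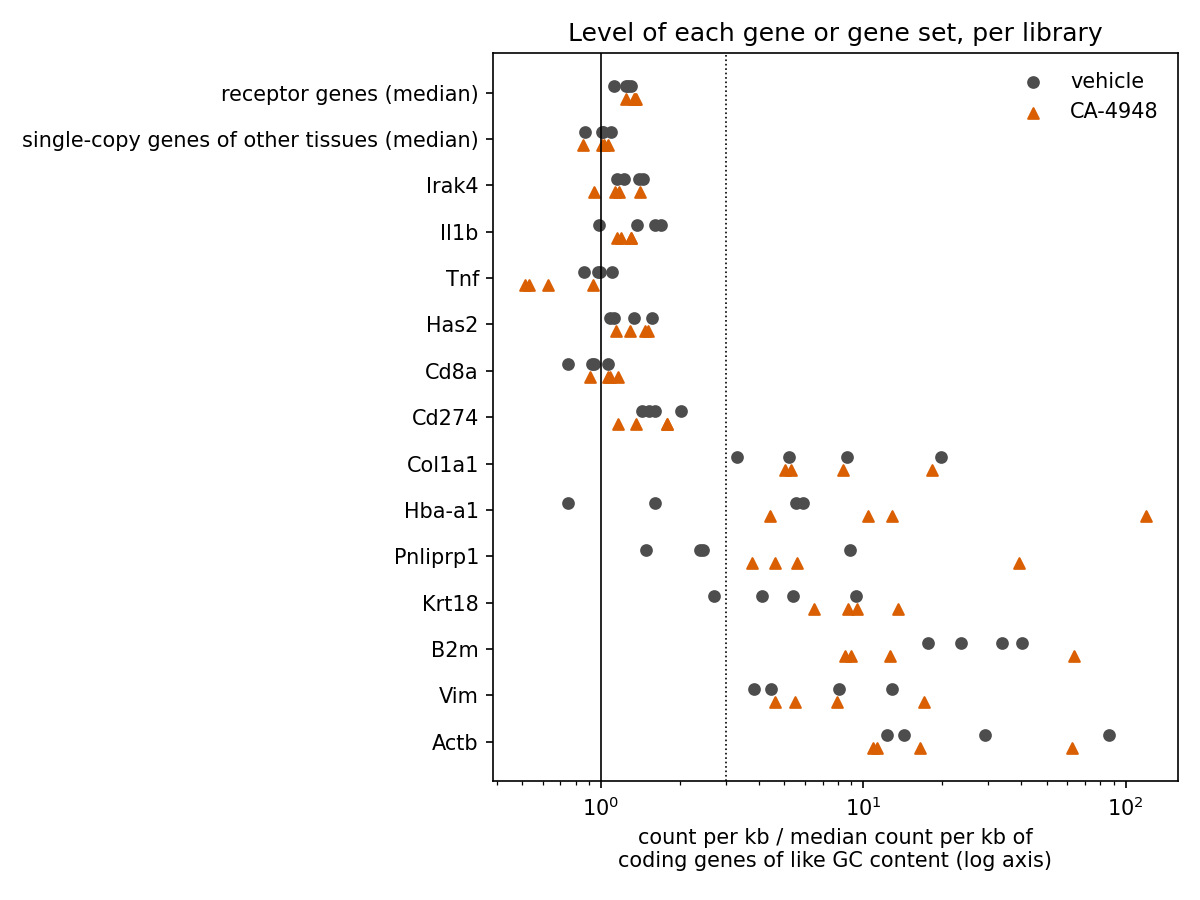
Relative level (counts per kilobase over the median of protein-coding genes of like GC content, log axis) of 13 single genes and the medians of 2 gene sets; each point is a library, circles for vehicle and triangles for CA-4948, and the lines mark 1 (solid) and 3 (dotted). Irak4, Il1b, Tnf, Has2, Cd8a and Cd274 lie between 0.511 (Tnf) and 2.02 (Cd274), while Col1a1, B2m and Actb lie above 3 in every library.

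Treated tumours had higher counts of 131 genes and lower counts of 332 among the 30858 tested. The largest increase among these was in Vaultrc5, a small vault RNA (ENSMUSG00000065145, chromosome 18, 36801866 to 36802008, 1 exon). It measured 1.48 ± 0.873 CPM in vehicle and 11.4 ± 3.83 CPM in CA-4948 (SD, n = 4 each), a log2 fold change of 2.95 ± 0.49 (SE) with an adjusted p of 0.0474. Hrh4, the histamine H4 receptor (ENSMUSG00000037346, chromosome 18, 13006990 to 13022882), rose from 2.29 ± 0.607 to 4.99 ± 0.965 CPM (log2 fold change 1.13 ± 0.23, adjusted p = 0.0121). Tnfrsf17, the B cell maturation antigen of plasma cells (ENSMUSG00000022496, chromosome 16, 11313812 to 11320074), rose by 1.09 ± 0.29 (adjusted p = 0.0437). The neighbouring genes Tctex1d1 (chromosome 4, 102986379 to 103005594) and Insl5, an insulin-like peptide (chromosome 4, 103017872 to 103026842), rose by 0.95 ± 0.16 and 0.98 ± 0.24. Spin2f (1.27), Apol10a (1.26) and Ctsr (1.00) completed the list with members of gene families whose copies can share reads. These were the olfactory receptors Olfr1306 (1.10) and Olfr1480 (1.03) and the secretoglobins Scgb2b11 (1.06) and Scgb2b21 (1.02), and their values are uncertain for that reason. With the GC correction, which was added after the data had been examined, Tctex1d1 alone of these named higher genes passed.

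Among the lower genes, Krtap12-1, a keratin-associated protein of hair (ENSMUSG00000069583, chromosome 10, 77720586 to 77721256), fell from 1.27 ± 0.420 to 0.361 ± 0.154 CPM. Its log2 fold change was -1.79 ± 0.46, with an adjusted p of 0.0391. Pnmt, the enzyme that makes adrenaline (ENSMUSG00000038216, chromosome 11, 98386450 to 98388181), fell from 2.42 ± 0.919 to 0.867 ± 0.332 CPM (log2 fold change -1.47 ± 0.34, adjusted p = 0.0263). Cirbp, the cold-inducible RNA-binding protein (ENSMUSG00000045193, chromosome 10, 80165985 to 80172786), fell from 2.73 ± 0.436 to 0.983 ± 0.507 CPM (log2 fold change -1.44 ± 0.32, adjusted p = 0.0198). Foxh1, a transcription factor of Nodal signalling, fell by 1.30 on the log2 scale, and Rnf126, a ubiquitin ligase, by 1.20. The other named genes were Gng13 (-1.58), Gipc3 (-1.47), Cnih2 (-1.40), Ufsp1 (-1.37), Prr19 (-1.33), Upk3bl (-1.26) and Jsrp1 (-1.26). With the GC correction none of these named lower genes passed.

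Most of the changed genes were counted near the level of genes that are not expressed, which is also near that of the median protein-coding gene. Such a level does not by itself show that the changed genes are silent, because the housekeeping gene Ppia had a mean relative level of 0.917. That rests on Ppia alone, as the other genes of the housekeeping index lay between 2.39 and 30.4. The 332 lower genes had a median relative level of 1.01, and 4 of the 331 with a known level reached 3. The 131 higher genes, of which 95 were protein-coding, had a median of 1.87, and 46 of the 128 with a known level reached 3. Among protein-coding genes 432 of 21277 reached 3, but the 46 include non-coding genes, so the 2 shares are not like for like. Of the 1378 receptor genes 85 also reached 3, so that level does not by itself mark expression. Receptor genes made up 13 of the 131 higher and 0 of the 332 lower genes. Among tested genes they made up 27% of the decile of lowest GC content and 0% of that of the highest, which held 184 of the lower genes. The 13 and 0 are therefore not a result about receptor genes apart from GC content. The 2 sets also differed in base composition, with a median transcript GC content of 43.5% for the higher and 57.3% for the lower genes, against 48.3% for all tested genes. Across genes, which are not independent replicates, log2 fold changes correlated with GC content at a Spearman rho of -0.445. The correlation of log counts per kilobase with GC content was 0.105 ± 0.0379 in vehicle and -0.0479 ± 0.0283 in CA-4948 tumours, with no overlap between the arms (two-sided exact permutation test, p = 0.0286, the smallest possible; adjusted p = 0.114 over 16 measures). With each library's GC trend removed, an analysis added after seeing the data, 11 higher and 3 lower genes passed, all of them among the 131 and 332.

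**Figure D2:**
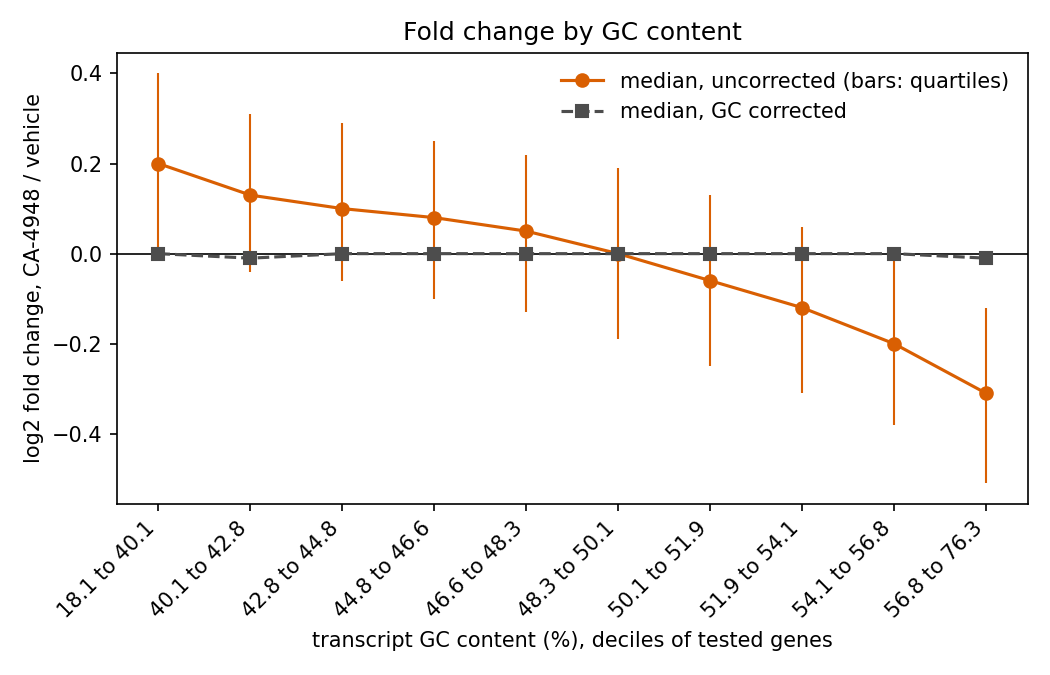
Median log2 fold change of CA-4948 over vehicle (vertical axis) in deciles of transcript GC content (horizontal axis, percent) for the tested genes, before and after the GC correction; vertical bars span the quartiles before correction. The uncorrected median runs from 0.20 in the decile of lowest GC content to -0.31 in that of the highest, and the corrected medians lie within 0.01 of 0.

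The count of changed genes was not stable. It fell to 7 higher and 5 lower genes without CA-4948 replicate 3, and by more than 1.5 times without vehicle replicate 1 (16 and 16), vehicle replicate 3 (21 and 41), CA-4948 replicate 1 (12 and 25) or CA-4948 replicate 4 (15 and 51). It was 16 and 18 with limma voom, and 6 and 9 with edgeR without robust estimation. The share of lower genes among the calls was 71.7% with TMM scaling, 49.0% with upper-quartile scaling and 99.7% by library size alone, which shifted the median of all genes by -0.34 on the log2 scale.

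NF-kB target genes, the transcripts expected downstream of IRAK4, were lower in CA-4948 tumours as a list (camera, adjusted p = 0.0402 over 34 lists; adjusted p = 0.885 with an estimated correlation). Of 31 members, 2 fell, 0 rose and 29 did not pass, while 3 were lower when adjusted over the list alone. Lif, a cytokine of the interleukin-6 family (ENSMUSG00000034394, chromosome 11, 4257557 to 4272514), fell from 5.14 ± 0.492 to 2.67 ± 0.713 CPM (log2 fold change -0.95 ± 0.21, adjusted p = 0.0226). Nfkb2, the precursor of a non-canonical NF-kB subunit (ENSMUSG00000025225, chromosome 19, 46304737 to 46312090), fell from 11.3 ± 1.63 to 6.78 ± 1.68 CPM (log2 fold change -0.73 ± 0.16, adjusted p = 0.0239). With the GC correction neither gene passed: Nfkb2 had a log2 fold change of -0.42 ± 0.16 (adjusted p = 0.352) and Lif one of -0.83 ± 0.21 (adjusted p = 0.133). Tnf measured 3.54 ± 0.423 in vehicle and 2.18 ± 0.643 CPM in CA-4948 (adjusted p = 0.143), and Nfkbie, an NF-kB inhibitor, 4.46 ± 0.747 and 2.75 ± 0.648 CPM (adjusted p = 0.107). Estimates were below 0 for 26 of the 31 members, with a median log2 fold change of -0.20. The members had a median relative level of 0.987 and 0 of them reached 3, with Lif at a mean of 0.421 and Nfkb2 at 1.58. The list missed the threshold without vehicle replicate 1 (0.0892), vehicle replicate 4 (0.108), CA-4948 replicate 1 (0.104) or CA-4948 replicate 4 (0.0531), and over the alternatives that change a single choice its adjusted p ranged from 0.00333 to 0.885. With both the GC correction and an estimated correlation it was 0.926. The list also missed the threshold with the acinar covariate (0.122) and with the housekeeping covariate (0.211), which was added after seeing the data. Its mean log2 CPM was 2.29, 2.00, 2.24 and 2.42 in vehicle replicates 1 to 4 and 1.90, 2.12, 2.02 and 2.02 in CA-4948 replicates 1 to 4, so the arms overlapped.

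**Figure D3:**
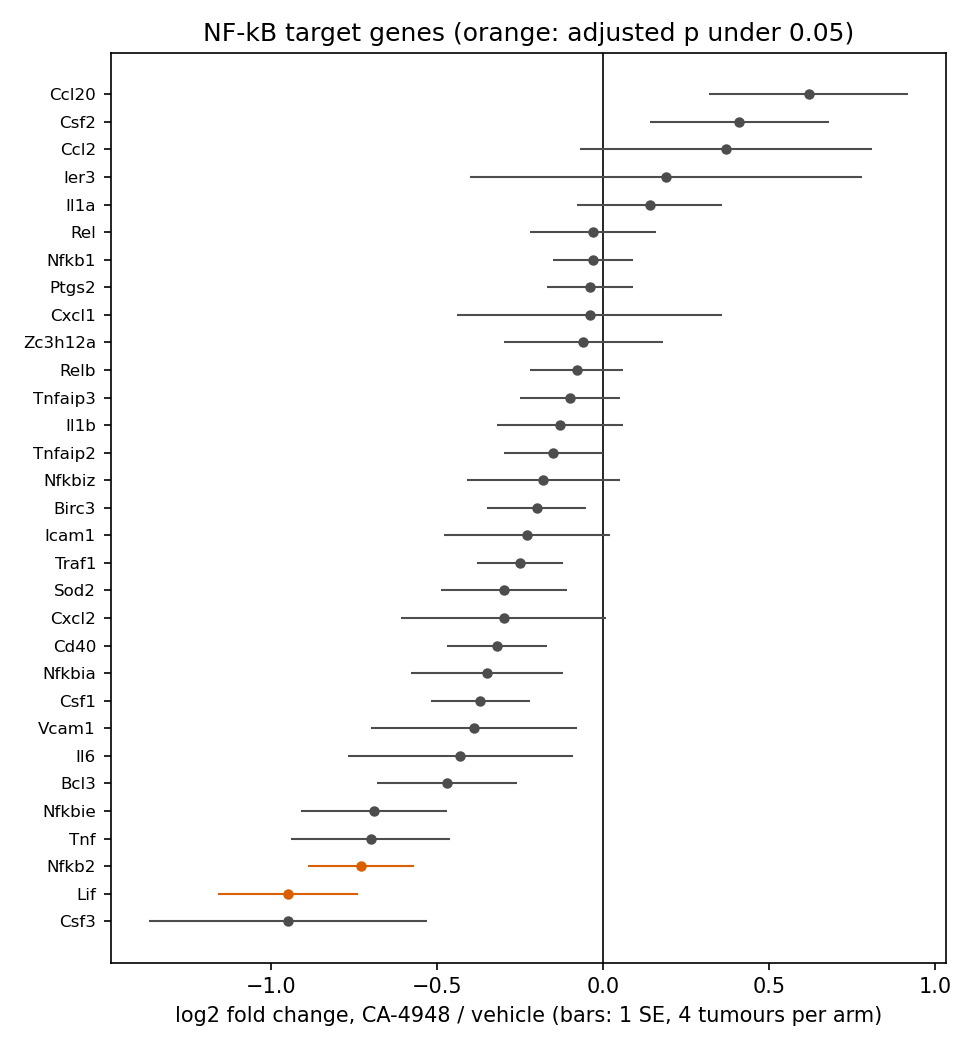
Log2 fold change of CA-4948 over vehicle (horizontal axis) for the 31 tested members of the NF-kB target list, with bars of 1 SE from 4 tumours per arm; orange marks an adjusted p under 0.05. Lif (-0.95) and Nfkb2 (-0.73) are marked, and 26 of the 31 estimates lie below 0.

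The receptor side of the pathway showed no change that passed. Irak4 itself (ENSMUSG00000059883, chromosome 15, 94543643 to 94581815) measured 14.1 ± 1.57 in vehicle and 12.5 ± 1.96 CPM in CA-4948 (log2 fold change -0.18 ± 0.13, adjusted p = 0.543). Irak1 had a log2 fold change of 0.10 ± 0.19 and the adaptor Myd88 one of -0.45 ± 0.26. Among the IRAK4 and MyD88 pathway components, 0 of 26 members passed and the list did not either (adjusted p = 0.928), with Il1rap at 0.34 ± 0.12 and Tlr4 at 0.33 ± 0.14. The inflammatory cytokines Il1b (-0.13 ± 0.19) and Il6 (-0.43 ± 0.34) and the neutrophil attractant Cxcl1 (-0.04 ± 0.40) did not pass. In the chemokine list 0 of 25 members passed (adjusted p = 0.966), among them Cxcl12 at 0.31 ± 0.12. The immediate early and stress genes came near the threshold on the lower side (adjusted p = 0.0584; 0.885 with an estimated correlation). None of its 14 members passed over all genes, and 2 were lower adjusted over the list alone. Hspa1b, a heat-shock protein, stood at -0.94 ± 0.28 and the nuclear receptor Nr4a1 at -0.72 ± 0.24.

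Acinar, Reg and globin transcripts varied widely between tumours of the same arm. The acinar, Reg and erythroid lists each reached an adjusted p of 0.0584 on the higher side, and 0.885 with an estimated correlation. In the acinar list 0 of 26 members passed. Pnliprp1, a pancreatic lipase-related protein, measured 13.5 ± 12 in vehicle and 45.5 ± 59.3 CPM in CA-4948, where replicate 1 stood at 134, and the acinar transcription factor Bhlha15 had a log2 fold change of -0.35 ± 0.18. In the list of Reg genes, which mark pancreatic injury, 0 of 6 passed, with Reg2 at 3.77 ± 4.22 and 17.9 ± 24.6 CPM and Reg1 at 6.72 ± 5.96 and 20.0 ± 22.0 CPM. In the erythroid list 0 of 8 passed. The globins Hba-a1 and Hbb-bs, whose near-identical copies can share reads, had log2 fold changes of 3.25 ± 1.35 and 3.44 ± 1.41, with CA-4948 replicate 2 at 167 and 174 CPM against at most 17.5 and 14.2 in the others of its arm. Islet markers gave 0 of 15 passing (adjusted p = 0.864; 1 higher adjusted over the list alone), with insulin transcript Ins2 at 0.96 ± 0.58 and glucagon transcript Gcg at 0.86 ± 0.24. Mitochondrially encoded genes gave 0 of 11 (adjusted p = 0.175; 0.885 with an estimated correlation), with 8 estimates above 0 and 3 below. They included mt-Nd5 at 0.58 ± 0.34, mt-Co1 at 0.44 ± 0.36, mt-Nd4 at 0.05 ± 0.53, mt-Nd1 at -0.01 ± 0.42 and mt-Nd3 at -0.23 ± 0.51. A separate measure was the share of counts over all genes of the mitochondrial chromosome, not only the tested list members. It was 0.625% ± 0.420 in vehicle and 0.325% ± 0.205 in CA-4948 tumours (SD, n = 4 each). The arms did not differ past the threshold (two-sided exact permutation test, p = 0.2, adjusted p = 0.457 over 16 measures).

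Stromal lists did not pass. Hyaluronan metabolism gave 0 of 15 members (adjusted p = 0.953), and the hyaluronan synthase Has2 measured 8 ± 1.69 in vehicle and 9.13 ± 0.995 CPM in CA-4948. Hyal2 stood at -0.47 ± 0.22 and Lyve1 at 0.30 ± 0.16. Collagens and matrix gave 0 of 26 (adjusted p = 0.742), with Col1a1 at 113 ± 84.1 and 92.3 ± 64.0 CPM, Col5a1 at -0.48 ± 0.32 and Fbn1 at 0.13 ± 0.10. Of the myofibroblast markers 0 of 16 passed (adjusted p = 0.260; 2 lower adjusted over the list alone), with Tgfb1 at -0.53 ± 0.17 and Pdgfrb at -0.41 ± 0.13. Among inflammatory fibroblast markers Lif was the 1 of 16 that fell (adjusted p of the list 0.344; 2 lower adjusted over the list alone), and Pi16 stood at -0.64 ± 0.19. Mesothelial markers gave 0 of 10 (adjusted p = 0.260; 1 lower adjusted over the list alone), with Rspo1 at -1.06 ± 0.30. Endothelial markers gave 0 of 14 (adjusted p = 0.641; 2 lower adjusted over the list alone), with Pecam1 at -0.37 ± 0.12.

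Immune lists did not pass either. T cell and cytotoxic markers gave 0 of 25 (adjusted p = 0.966; 1 higher adjusted over the list alone), with Cd8a at 5.91 ± 0.910 in vehicle and 6.88 ± 0.723 CPM in CA-4948. Icos stood at 0.56 ± 0.16 and Nkg7 at -0.99 ± 0.37. Exhaustion and checkpoint genes gave 0 of 17 (adjusted p = 0.953), with Pdcd1 at 0.41 ± 0.21, Cd274 at -0.05 ± 0.15 and Vsir at -0.43 ± 0.15. Regulatory T cell markers gave 0 of 10 (adjusted p = 0.661), with Foxp3 at -0.11 ± 0.17 and Ctla4 at 0.28 ± 0.17. Tnfrsf17 was the 1 of 16 B cell and plasma cell markers that rose (adjusted p of the list 0.864; 1 higher adjusted over the list alone), while Cd79a stood at -0.73 ± 0.35. NK cell markers gave 0 of 10 (adjusted p = 0.912), with Klrc1 at 0.69 ± 0.33 and Klre1 at -0.52 ± 0.29. Macrophage markers gave 0 of 20 (adjusted p = 0.953), with Cd68 at -0.39 ± 0.15 and Marco at 0.38 ± 0.17. Among neutrophil markers, Mmp9, a matrix metalloproteinase, was the 1 of 20 that fell (log2 fold change -0.51 ± 0.14, adjusted p = 0.0488). With the GC correction Mmp9 stood at -0.32 ± 0.14 and did not pass (adjusted p = 0.406). The neutrophil list had an adjusted p of 0.599, with 1 member lower adjusted over the list alone, and Lcn2 stood at -1.18 ± 0.44. Dendritic cell markers gave 0 of 13 (adjusted p = 0.864), with Cadm1 at 0.22 ± 0.10 and Ccr7 at -0.51 ± 0.24. Antigen presentation genes gave 0 of 21 (adjusted p = 0.346), with Nlrc5 at -0.31 ± 0.13 and Tap1 at -0.30 ± 0.14. Interferon response genes gave 0 of 31 (adjusted p = 0.661), with Oasl1 at -0.52 ± 0.18 and Gbp2 at 0.32 ± 0.14.

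The lists for the tumour cells themselves did not pass. Cell cycle genes gave 0 of 29 (adjusted p = 0.966), with Cenpe at 0.31 ± 0.12 and Mcm6 at 0.31 ± 0.13. In the p53 list Zmat3, an RNA-binding p53 target, was the 1 of 17 that rose (log2 fold change 0.49 ± 0.12, adjusted p = 0.0306; list 0.822, 1 higher adjusted over the list alone), and Cdkn1a stood at -0.38 ± 0.22. Hypoxia and glycolysis genes gave 0 of 21 (adjusted p = 0.137), with the glucose transporter Slc2a1 at -0.82 ± 0.40 and Vegfa at -0.74 ± 0.45. KRAS and MAPK output genes gave 0 of 20 (adjusted p = 0.260; 2 lower adjusted over the list alone), with Epha2 at -0.62 ± 0.17 and Fosl1 at -0.81 ± 0.26. Kras had a log2 fold change of -0.02 ± 0.28 and Cdkn2a, the gene of INK4A, one of -0.44 ± 0.26. Ductal epithelial genes gave 0 of 22 (adjusted p = 0.175; 1 higher and 1 lower adjusted over the list alone), with Prom1 at 0.34 ± 0.10 and Hnf1b at -0.55 ± 0.17. In the epithelial-mesenchymal transition list Cdh11, a mesenchymal cadherin, was the 1 of 15 that rose (log2 fold change 0.54 ± 0.13, adjusted p = 0.0323, list 0.895, 1 higher adjusted over the list alone). With the GC correction Zmat3 stood at 0.44 and Cdh11 at 0.45, and neither passed.

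Markers of other neighbouring tissues gave 1 member each. Plin1, the lipid droplet protein of fat cells, fell by 1.09 on the log2 scale (SE 0.26, adjusted p = 0.0308; adipocyte list 0.346, 3 lower adjusted over the list alone). Actn3, an actinin of fast skeletal muscle, fell by 0.57 (SE 0.14, adjusted p = 0.0366; skeletal muscle list 0.140, 2 lower adjusted over the list alone). Sis, the intestinal sucrase-isomaltase, rose by 0.68 ± 0.16 (adjusted p = 0.0325; gut and liver list 0.895, 1 higher adjusted over the list alone), while Alb stood at 0.37 ± 0.16. With the GC correction Plin1 stood at -0.84, Actn3 at -0.33 and Sis at 0.54, and none of these genes passed. In 9 of the 34 lists, none of them past the threshold, the median, the mean and the test's direction differed in sign or a mean rounded to 0. Of the sex-linked genes too few were kept for a test, and Xist had 428 to 1110 counts per library.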

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

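Tests of unspliced RNA, of GC content and of the level of the NF-kB members were chosen after the result was seen; the tests on X-linked and single-copy genes, on splits of the samples and on random lists were written before, and the reading of the X-linked test was made stricter after its value was seen, so that every library had to lie within its bounds.

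Of 276 groups of 4 libraries examined for a library far from the others, 20 stood out where chance gives about 13.8. The gap to the nearest library over the range of the group is given as a ratio, and gene values are CPM. In CA-4948 replicate 2, the mitochondrial share of counts was 0.632% against 0.206% to 0.234% (ratio 0.933) and the housekeeping index 13.4 against 3.13 to 4.75 (0.842). The globin Hba-a1 stood there at 167 against 5.81 to 17.5 (0.927), Hbb-bs at 174 against 4.75 to 14.2 (0.944) and Col5a1 at 36.8 against 20.5 to 22.3 (0.89). The mean log2 CPM of the hypoxia and glycolysis list was 3.98 against 3.36 to 3.42 (0.898). In CA-4948 replicate 1, Pnliprp1 stood at 134 against 12.7 to 19 (0.948), Reg2 at 54.7 against 4.27 to 6.78 (0.95) and mt-Nd5, a low value, at 351 against 561 to 585 (0.897). CA-4948 replicate 4 stood high for Insl5, at 4.88 against 3.32 to 3.58 (0.833), and for Nfkbie, at 3.71 against 2.35 to 2.56 (0.843).

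Vehicle replicate 4 stood high for Slc2a1, at 27.6 against 12.3 to 13.4 (0.926), Rnf126, at 4.97 against 2.93 to 3.21 (0.861), and Nr4a1, at 4.64 against 3.08 to 3.29 (0.866). The mean log2 CPM of its ductal list was 3.36 against 2.96 to 3.02 (0.843). In vehicle replicate 2, Pnliprp1 stood at 31.4 against 5.39 to 8.79 (0.87) and Scgb2b21 at 2.9 against 1.91 to 2.05 (0.857). In vehicle replicate 3, Tnfrsf17 stood at 2.12 against 1.08 to 1.26 (0.833) and Alb at 8.21 against 5.72 to 5.84 (0.954). In vehicle replicate 1, Hspa1b stood at 3.32 against 2.68 to 2.78 (0.839).

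Smell and taste receptor genes carried counts at 1.12 to 1.36 times the level of protein-coding genes of like GC content in every library. Reads shared between receptor copies are argued against by 29 single-copy genes of retina, germ cells, pituitary, kidney, lung, teeth and brain, whose median relative level was 1.01 (quartiles 0.782 and 1.16). The same 29 genes argue against unspliced RNA of transcribed genes as the whole source, as far as these tumours do not transcribe them. Genomic DNA in the libraries stays a possible explanation. X-linked receptor genes had 0.769 of the autosomal level, and 4 Y-linked genes had a median relative level of 0.0692. By the rule written before the result was seen, these values go with genomic DNA. Only 9 X-linked receptor genes were counted, however, and the libraries ranged from 0.641 to 0.978. Under the stricter reading made afterwards, the test therefore does not decide. No biological explanation was tested.

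The 131 higher and 332 lower genes differed in GC content. Of the 35 splits of the 8 libraries 1, the real one, gave as many called genes. By the rule written before, under 0.05 of the splits giving as many argues against chance for their number, and this was met. The result is also the fewest the test can give, so chance is not excluded. The highest of the other splits gave 242, and it parts the 4 libraries of highest housekeeping index from the rest. GC content as the whole cause is argued against for 14 genes that stayed past the threshold after the correction, but chance cannot be excluded for their number, because 4 of the 35 splits gave as many and the highest other gave 201. That was again the split by housekeeping index, which points to a structure of the samples whose cause was not tested. For the 449 genes that lost their call, the median fold went from 0.674 to 0.465 on the log2 scale while its SE went from 0.158 to 0.155, and the fold shrank for 421 of them. For the other 28 it did not, so those calls did not end through a smaller fold. Among them was Tnfrsf17, whose adjusted p went from 0.0437 to 0.115 while its log2 fold change went from 1.09 to 1.15. Its unadjusted p (quasi-likelihood F test) went from 0.000523 to 0.000282, so its call ended through the adjustment over all genes. Over all tested genes, those at an unadjusted p under 0.05 went from 4734 to 3210. Of the 449 genes 389 stayed at an unadjusted p under 0.05 and 0 changed sign. In simulated counts without changed genes, the GC trends of these libraries gave 14 calls among 30241 genes, and 1 after the correction, a bound from simulated settings that excludes nothing in the real libraries. The GC trend follows the arms and the genes were picked for their folds, so for these genes a treatment effect and a difference in library preparation cannot be told apart.

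The NF-kB list was lower in CA-4948 tumours. GC content as the whole cause is argued against by its adjusted p of 0.0228 after the correction with the preset correlation; with an estimated correlation it passed neither before (0.885) nor after it (0.926). A fall common to genes of like GC content and level is argued against by 10000 matched random lists, of which 0.03% had a mean as low, although random lists lack the correlation between members. Counts that are background rather than transcripts remain a possible explanation for the members' values, whose median relative level was 0.987. That level does not decide, because the housekeeping gene Ppia had a mean relative level of 0.917. The other genes of the housekeeping index lay between 2.39 and 30.4, so this limit rests on Ppia alone. For the number of lists past the threshold chance cannot be excluded: 31 of the 35 splits gave at least 1 list, and the highest other gave 15. An effect of IRAK4 inhibition on these genes stays open.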

How the results depend on the processing

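Tests with the GC correction, the relative-level restriction, the housekeeping covariate and the omission of vehicle replicate 4 and CA-4948 replicate 2, the libraries with the highest housekeeping index in their arms (16.4 and 13.4), were chosen after the data had been seen. The cause of a change was not tested unless stated. The 131 higher and 332 lower genes became 16 and 4846 by library size alone, 201 and 193 with upper-quartile scaling, 16 and 18 with limma voom, 6 and 9 without robust estimation and 24 and 65 with the acinar covariate. They became 11 and 3 with the GC correction, 291 and 493 with the housekeeping covariate, and 298 and 631 without the 2 libraries named above. Among genes at a relative level of at least 3 they were 0 and 0 of 432 with edgeR, with 39 at an unadjusted p under 0.05 and a smallest adjusted p of 0.358. No other tool was run on these genes. That fit scaled the libraries on these genes alone, which shifted their median log2 fold change by -0.13. In the fit of all genes, 46 higher and 4 lower genes at this level passed, non-coding genes included. How many of the 432 were among these was not counted, but Ednra and Sfi1 were. The 0 calls therefore do not show that the 432 genes were unchanged. Of the 432 genes 85 were receptor genes, so they are not simply expressed genes. A threshold of 0.1 gave 327 and 645, and a minimum absolute log2 fold change of 1 gave 17 and 38, both by construction. Leaving out each library gave 7 to 180 higher and 5 to 419 lower genes. DESeq2 size factors, the DESeq2 Wald test, both other filters and the removal of marker genes kept both counts within 1.5 times. With the replicate block the counts were 6 and 10, and the NF-kB list reached 0.0556. Deviations of samples with the same number correlated at -0.01, -0.17, 0.05 and -0.09, and no sample of the vehicle arm correlated best with its own number. These values gave no sign of pairing by number, but with 4 samples per arm they cannot exclude it.

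The NF-kB list stayed lower in all 22 alternatives run on it. Its adjusted p was 0.885 with an estimated correlation, 0.285 with fry, 0.122 with the acinar covariate, 0.211 with the housekeeping covariate and 0.00333 to 0.108 with each library left out. Other lists crossed the threshold in some alternatives, all at the preset correlation. With TMM scaling and an estimated correlation the acinar (estimate 0.693), Reg (0.565), erythroid (0.166) and mitochondrial (0.805) lists had an adjusted p of 0.885 each, and collagens and matrix (0.809) one of 0.982; the correlation was not estimated in the other alternatives except the GC correction. By library size alone the acinar (2.95e-07), Reg (0.00019), erythroid (0.00019) and mitochondrial (0.012) lists were higher. With limma voom the acinar, Reg and erythroid lists (0.0312 each) and the mitochondrial list (0.0341) were higher, and the hypoxia and immediate early lists (0.045 each) lower. With the GC correction the acinar (0.0164) and erythroid (0.0197) lists were higher, but at 0.926 each, like the NF-kB list, when the correlation was also estimated. Among genes at a relative level of at least 3 the acinar list was higher (0.0258). That set was chosen by the mean over both arms. Its acinar members Try4, Zg16 and Gp2 had vehicle means of 1.56, 2.57 and 2.44, the others means above 3. In CA-4948 replicate 1 these genes stood at 12.2, 13.7 and 13.6. The restriction thus favours members high in CA-4948, and this result is not separate support. With the housekeeping covariate the erythroid (0.0053) and mitochondrial (0.00261) lists were higher, and collagens and matrix (0.0053) turned from lower to higher, at the preset correlation. Without the 2 libraries named above, antigen presentation (0.0126) and hypoxia (0.0481) were lower and the Reg (0.0481) and mitochondrial (0.00594) lists higher.

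With each library left out, adjusted p ranged from 1.42e-05 to 0.872 for the acinar, 0.00482 to 0.323 for the Reg, 0.0195 to 0.125 for the erythroid and 0.000111 to 0.677 for the mitochondrial list. It ranged from 0.0123 to 0.872 for antigen presentation, 0.0205 to 0.986 for collagens, 0.0225 to 0.576 for ductal, 0.00752 to 0.681 for hypoxia, 0.0205 to 0.264 for immediate early, 0.0449 to 0.671 for KRAS output and 0.0407 to 0.742 for myofibroblast genes. Omission of CA-4948 replicate 2 took each of these 7 past the threshold, as did that of vehicle replicate 3 for hypoxia and immediate early genes. The acinar and Reg lists passed without vehicle replicate 2, CA-4948 replicate 2 or CA-4948 replicate 3, the erythroid list without vehicle replicate 2, vehicle replicate 3 or CA-4948 replicate 3, and the mitochondrial list without vehicle replicate 4. The NF-kB list was lost without vehicle replicate 1, vehicle replicate 4, CA-4948 replicate 1 or CA-4948 replicate 4. The other 22 lists passed in no alternative. Of the 32 named genes past the threshold, 31 kept their call with DESeq2 size factors, 27 with upper-quartile scaling, 2 with limma voom, 4 with the acinar covariate, 2 without robust estimation, and 1 each with the GC correction and the replicate block. Without CA-4948 replicate 3 0 kept it, without vehicle replicate 3 1 and without vehicle replicate 1 2. None of them changed sign while past the threshold in any of the 23 alternatives. Signs changed in 41 gene and 64 list values that passed in neither fit.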

Other observations

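The ratio of housekeeping to receptor gene counts differed between tumours of an arm. This housekeeping index was 9.56, 4.71, 5.31 and 16.4 in vehicle replicates 1 to 4 and 4.75, 13.4, 3.16 and 3.13 in CA-4948 replicates 1 to 4 (two-sided exact permutation test, p = 0.486, n = 4 each; adjusted p = 0.648 over 16 measures). Fn1, the fibronectin gene, varied widely and measured 463 ± 441 CPM in vehicle and 236 ± 157 in CA-4948, and Spp1, osteopontin, 45.4 ± 41.0 and 36.3 ± 32.3 (SD, n = 4 each). Of the acinar markers 15 of 26 reached a relative level of 3, with Ctrb1, a chymotrypsinogen, at 98.1 ± 166 and 140 ± 134 CPM. These 3 genes were picked after their values were seen, and none passed the test.

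Of the 14 genes past the threshold with and without the GC correction, which was added after the data had been seen, 5 were protein-coding. Ednra, the endothelin A receptor (ENSMUSG00000031616, chromosome 8, 77663031 to 77724464), measured 28.3 ± 1.15 CPM in vehicle and 42.8 ± 3.68 in CA-4948, with a corrected log2 fold change of 0.54 ± 0.09 and an adjusted p of 0.00461. Rasgrp2, an exchange factor of Rap1 in platelets (ENSMUSG00000032946, chromosome 19, 6399340 to 6415216), measured 28.0 ± 1.54 and 18.0 ± 2.19 CPM, with a corrected log2 fold change of -0.62 ± 0.11 and an adjusted p of 0.0067. Thsd7b, Tctex1d1 and Sfi1 had corrected log2 fold changes of 0.47, 0.80 and 0.48. Among the 432 genes at a relative level of at least 3, fitted on their own without the GC correction, Ednra (log2 fold change 0.47 ± 0.26) and Sfi1 (0.19 ± 0.24) did not pass, the smallest adjusted p of any of them being 0.358. Chance was not excluded for the number of 14. Rasgrp2 had a mean relative level of 0.852, below the receptor gene medians of 1.12 to 1.36 per library, and Thsd7b one of 1.32, within their range. Apart from Tctex1d1 these genes lie outside the rule for named genes. Among low counts of 1 to 29, even numbers made up 59.5% to 62.7% of values per library. Whether the reads of a pair were counted separately is not given in the sources used here, so the number of independent fragments behind a count, and the width of a counting interval, are uncertain.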
